A study of Mus musculus with 10 samples.

How the data were processed

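Total RNA of MEL cells was measured on 10 Affymetrix Mouse Genome 430 2.0 arrays, 2 of the parental BirA line and 2 of each of 4 subclones with tagged BCL11A. Per the labels' protocols, cDNA made with an oligo-dT primer was transcribed in vitro into biotin-labelled cRNA, which was stained with a streptavidin dye conjugate. The deposited values are linear probe set intensities, all above 0, with array medians close together. How probes were summarised, corrected for background and scaled is not given in the sources used here. Groups come from the sample titles and source names. Nothing states that the 2 arrays of a line came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. No 2 arrays held identical values. The number of arrays limits the precision, with 2 per line.

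All 45101 probe sets were read, and 64 control probe sets were left out. Values were taken as log2(intensity + 16), so a fold understates the change of dim genes. Array medians on this scale differed by 0.0623, under the limit of 0.2 set beforehand, so no further normalization was applied. A probe set was tested if it exceeded the median of the table, 30.5, in at least 2 of the 10 arrays, which left 25061. Where an array of the dimmer line lay at or below that median, used as the background level, the fold is a lower bound, written as at least N-fold. It sets the mean log2 intensity of the brighter line, without the 16, against that of the dimmer with each array raised to the median where it lay below, and means of the 4 subclones weight each alike. Fitted log2 differences of such genes depend on the 16 added. Gene names come from the platform annotation. Of all probe sets 34958 have 1 gene symbol, 932 several and 9211 none, and of the tested ones 21193, 583 and 3285. Of the probe sets with 1 symbol, 34754 of 34958 matched a RefSeq gene of assembly GRCm38.p6 through the gene identifier, and 0 symbols changed. That table was used for names, for chromosomes and for which genes neighbour each other, and no reference genome was used here. Genes of the lists without a tested probe set of their own were not analysed here.

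Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures drawn in Python 3.11.15 with matplotlib 3.10.9. Tagged arrays were set against parental with the cell line as a random block (duplicateCorrelation, consensus correlation 0.211), eBayes with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. Each subclone was set against parental, and the subclones against each other by a moderated F test with 3 contrasts, in a fit of 5 line means that pools the spread over the lines (5 residual degrees of freedom and 9.92 from the prior). Where an array is left out, the remaining array of its line is assumed to vary like the other lines. Gene lists were tested by cameraPR on 1 probe set per gene, the one with the highest mean, with an inter-gene correlation of 0.01 and with the estimated correlation beside it, and lists with fewer than 3 measured members were not tested. The 22 lists, the tests and the rule for named genes were fixed before the data were examined. The list tests in single subclones use the 5-line fit and were added after the data were seen, as were all values by chromosome.

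The rule named Bcl11a and every globin gene, the 12 highest and 12 lowest passing genes of tagged against parental with all 4 subclones on one side, up to 4 members of each list with the smallest p, the 3 highest and 3 lowest genes of each subclone that passed in no other, and the 10 genes with the smallest F test p. As no gene passed with the line as a block, the first part was applied to the fit of 5 line means, which was fixed in advance as well. Genes were ranked by their brightest probe set. Genes named because they passed in all 4 subclones and the genes named by chromosome were chosen after their values were seen. So were Hspa5, Hsph1, Tpsb2, Khnyn, Nynrin, Sdr39u1, Atp12a, Sptb, Rhag, Zfpm1, Tcf3 and Ddit3. A ratio of the differences from the 2 parental arrays had been written down in advance as a test of RNA quality and was dropped, because probe sets called with both arrays favour a ratio near 1. Functions were tested on simulated data with 200 changed probe sets among 25061, in which probe sets of like intensity were given the same spread. For FBB1.5 against parental, 50 of 50 changed by 1 on the log2 scale and 30 of 50 changed by 0.5 were recovered, with 6 false calls. For the F test between subclones the values were 49 and 33 of 50, with 14 false calls. When clones varied as well, the fit of 5 line means made 111 false calls and the fit with the line as a block 12. Alternatives covered the pseudocount (1 or 64), quantile normalization or median centring, 3 other filters, 2 other variance models, the replicate number as a block, a 1.5-fold minimum, other treatments of the cell line, and each array or subclone left out.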

Results

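Gene expression was measured in mouse erythroleukemia (MEL) cells, virus-transformed red cell precursors that grow in culture, on 10 Affymetrix Mouse Genome 430 2.0 arrays. The parental line, which carries the bacterial biotin ligase BirA, was measured on 2 arrays. Each of 4 subclones that also carry BCL11A with a FLAG and biotin tag (FBB1.5, FBB1.7, FBB1.10 and FBB1.11) was measured on 2 arrays, which gives 8 tagged arrays. BCL11A is a zinc finger transcription factor known as a repressor of embryonic and fetal globin genes. The labels imply one question, namely which transcripts differ between cells with the tagged protein and their parental line, and the 4 subclones add how far clones with the same construct differ from each other. Of 45101 probe sets, 25061 passed the intensity filter, and these name 12502 genes. The median intensity of an array lay between 29.6 and 31.6. Over the tested probe sets, Pearson's r was 0.981 to 0.989 for arrays of one line and 0.968 to 0.987 for arrays of different lines, across genes, which are not independent replicates. The parental pair was the least alike of the 5 same-line pairs, at 0.981. Parental 1 was closer to several subclone arrays than to parental 2, with r up to 0.985 for FBB1.11 2. The ratio of the 3' to the 5' actin control probe set, a sign of RNA quality, was 1.80 in parental 2 and 1.47 in FBB1.5 1, against 1.06 to 1.22 in the other 8 arrays.

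Bcl11a itself was read by 7 probe sets, and 1 of them was higher in 3 of the 4 subclones. Its intensity was 37.8 ± 2.69 in parental cells (SD, n = 2), 79.0 ± 23.9 in FBB1.5, 63.7 ± 1.88 in FBB1.7, 199 ± 48.2 in FBB1.10 and 213 ± 45.8 in FBB1.11. The log2 difference from parental was 1.98 ± 0.19 (SE) in FBB1.10 and 2.08 ± 0.19 in FBB1.11, with limma's adjusted p = 0.00017 and 7.1e-05. It was 0.80 ± 0.19 in FBB1.5 (adjusted p = 0.041) and 0.57 ± 0.19 in FBB1.7 (adjusted p = 0.071, which misses the threshold). This Bcl11a probe set differed between the 4 subclones (moderated F test, adjusted p = 0.00024). A brighter Bcl11a probe set fell in FBB1.7, from 329.8 ± 28.6 to 233 ± 5.02 (adjusted p = 0.015), and did not pass in the other 3 subclones. The remaining 4 tested Bcl11a probe sets passed in no subclone and 1 lay below the filter. Of these 4, 1 rose in FBB1.7 by 0.46 on the log2 scale (adjusted p = 0.077) and passed only without FBB1.5 1 or FBB1.5 2. The calls of the first probe set in FBB1.10 and FBB1.11 held whichever array was left out. The call in FBB1.5 ended without parental 1, parental 2, FBB1.5 2, FBB1.7 1 or FBB1.7 2 (adjusted p up to 0.32), and FBB1.7 passed without FBB1.5 1 or FBB1.5 2 (lowest adjusted p 0.045). The fall of the brighter one in FBB1.7 ended without parental 2, FBB1.7 1 or FBB1.7 2 (adjusted p up to 0.11). Which of the 7 probe sets can read the introduced construct was not analysed here.

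**Figure D1:**
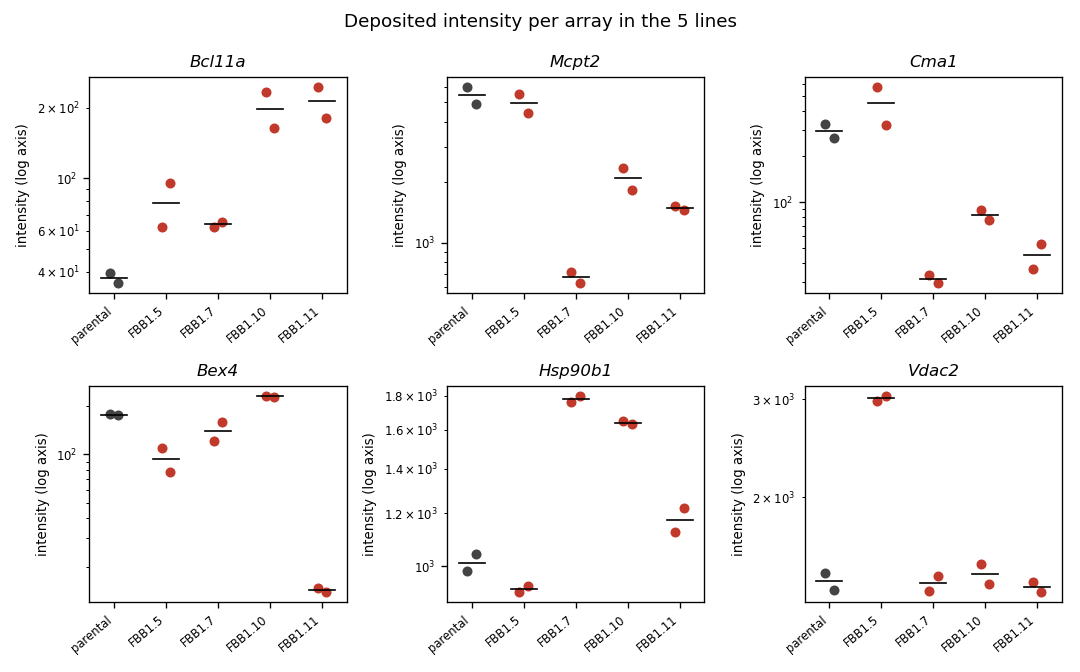
Deposited intensity per array (log axis) of the Bcl11a probe set that differed most between subclones and of Mcpt2, Cma1, Bex4, Hsp90b1 and Vdac2, in the parental line (grey) and the 4 subclones (red). Each point is 1 array and each bar the mean of the 2 arrays of a line, and Mcpt2 runs from 673 in FBB1.7 to 5453 in parental cells.

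Across all tagged arrays against the parental line, transcripts of a mast cell protease, a histone gene and a phosphatase were among the furthest apart. Mcpt2, a mast cell chymase, had an intensity of 5453 ± 736 in parental cells (SD, n = 2) and 4988, 673, 2096 and 1487 in FBB1.5, FBB1.7, FBB1.10 and FBB1.11. H1f2, a linker histone, had 613 ± 81.4 in parental cells and between 269 and 376 in the subclones. Dusp7, a phosphatase that acts on ERK kinases, had 35.2 ± 29.7 in parental cells and between 98.8 and 174 in the subclones. With the cell line as a random block, none of the 25061 probe sets passed limma's test at an adjusted p of 0.05. The smallest adjusted p was 0.16, and 2190 probe sets had an unadjusted p under 0.05, against 1253 by chance. In simulated data of the same size with a spread between lines, this test recovered 48 of 50 probe sets changed by 1 on the log2 scale and 30 of 50 changed by 0.5. That simulation gave probe sets of like intensity the same spread, so its recovery need not hold for these data. Here a Kif3b probe set with a log2 difference of 1.72 had an adjusted p of 0.16 by this test. H1f2, at -0.95, had an adjusted p of 0.25. Without parental 1, 128 probe sets passed (118 higher), against 2 without parental 2 and 2 without FBB1.5 1. Without both arrays of FBB1.5, 31 passed.

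When the spread was taken only from arrays of the same line, in a fit of 5 line means, the mean of the 4 subclones differed from parental for 887 probe sets, 497 higher and 390 lower (346 and 451 with each array centred on its median), of which 841 had all 4 subclones on the same side. Choice by the mean over these same 4 subclones, against shared parental arrays, favours such agreement. Of the 887 probe sets, 359 also differed between the subclones in the F test. This fit treats the clones as fixed and says nothing about further clones. In it, Mcpt2 fell by 1.59 on the log2 scale (SE 0.10, adjusted p = 1.2e-06), H1f2 by 0.95 (adjusted p = 0.00069) and Plac8 by 0.81 (adjusted p = 0.0034). Ndrg1, a gene induced by stress and differentiation, decreased by 0.78 (adjusted p = 0.0019), and 4 of its 5 probe sets passed in this direction. The calcium-binding protein gene S100a1 decreased by 0.93 (adjusted p = 0.0051) and Vwf, the von Willebrand factor gene, fell at least 1.67-fold (adjusted p = 0.030). Of the 8 tagged arrays, 6 read Vwf and 1 read Plac8 at or below the table median, where an intensity is only an upper bound. Tas2r119, 1700129C05Rik, Ermard, N4bp2l1, Cog1 and Gm5600 were also among the 12 lowest. Of these, Tas2r119 and 1700129C05Rik lay at or below the table median on all 8 tagged arrays, and N4bp2l1 and Gm5600 on some. The rank of such genes depends on the 16 added. Dusp7, at or below that median on 1 of 2 parental arrays, rose at least 3.25-fold (adjusted p = 0.0041), Cda, cytidine deaminase, by 0.81 ± 0.10 on the log2 scale (SE, adjusted p = 0.00079) and Pdia6, a protein disulfide isomerase of the endoplasmic reticulum, by 0.68 ± 0.092 (adjusted p = 0.0013). Fbp2, a gluconeogenic enzyme gene, rose by 0.67 ± 0.11 (adjusted p = 0.0053) and the amino acid transporter gene Slc1a4 by 0.63 ± 0.11 (adjusted p = 0.0085), and 6820431F20Rik, Pcare, Hcn2, Nap1l2, Rassf2, Rtn4rl2 and Osbpl6 completed the 12 highest. Pcare, Hcn2, Nap1l2 and Osbpl6 lay at or below the table median on both parental arrays and Rassf2 on parental 2, so their rank depends on the 16 added. Hcn2 and Nap1l2 lay there on most tagged arrays too. This ranking takes the brightest probe set of each gene. Among probe sets that are not their gene's brightest, 1 of Kif3b rose at least 4.19-fold and 1 of Trip11 at least 2.24-fold, each at or below the table median on 1 of 2 parental arrays. On the log2 scale 1 of Phf3 rose by 0.95 and 1 of Igf1r by 0.69, and 1 of Ube2h fell by 0.81, all of which passed as well. Probe sets of one gene often disagreed, with 1 of 2 passing for Dusp7, 1 of 2 for Pdia6, 2 of 3 for H1f2 and 1 of 5 for Cog1. For S100a1, N4bp2l1 and Ermard 1 of 2 passed, for Rassf2 1 of 3 and for Slc1a4 2 of 3. The second probe set of S100a1 stood at -0.13 on the log2 scale. A probe set of H1f2 stood at 0.16, 1 of Cog1 at 0.041 and 1 of N4bp2l1 at 0.025, above 0. Whichever array was left out, Cda, Pdia6, Mcpt2, H1f2, S100a1, N4bp2l1, Cog1, Plac8 and Ndrg1 passed. The fitted log2 difference of Dusp7 was 1.07 without parental 2 and 2.33 without parental 1. Dusp7, Fbp2, Rassf2, Slc1a4, Tas2r119 and Ermard lost their call without parental 2 alone (adjusted p 0.052 to 0.30), Vwf without parental 1, FBB1.5 2, FBB1.10 1 or FBB1.11 1 (adjusted p up to 0.24), and the remaining 8 without 2 or more arrays, parental 2 among them for each. The count was 351 without parental 2 and 476 to 585 without any one of FBB1.7 1, FBB1.7 2, FBB1.10 2, FBB1.11 1 or FBB1.11 2. It was 334 with no intensity filter, 25 without the intensity trend in the variance, and 198 with the actin ratio as a covariate, an alternative added after the data were seen.

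**Figure D2:**
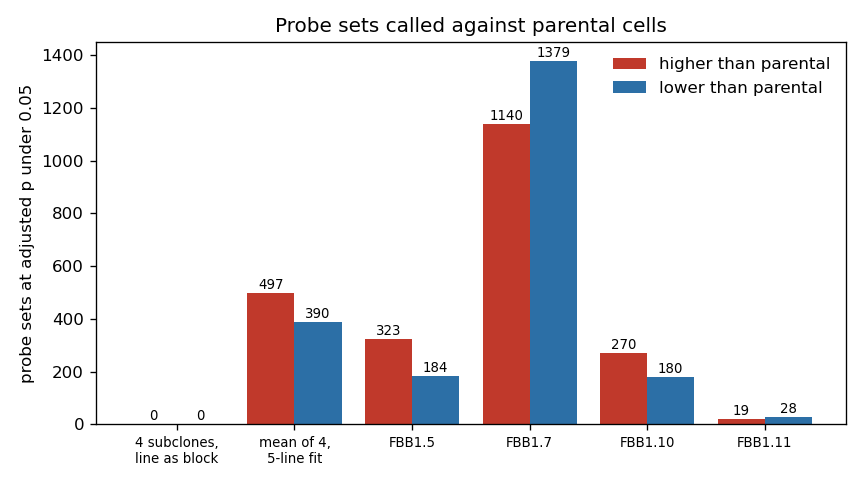
Number of probe sets higher (red) or lower (blue) than in parental cells at an adjusted p under 0.05, for all tagged arrays with the line as a block, for the mean of the 4 subclones in the fit of 5 line means, and for each subclone. FBB1.7 has the tallest bars, with 1140 higher and 1379 lower.

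Of the globin genes, adult alpha-globin was higher in FBB1.7 on all 4 tested probe sets, in FBB1.5 on 2 and in FBB1.10 on 1, and the embryonic beta-like genes were not detected above the filter. The brightest probe set shared by the adult alpha-globin genes Hba-a1 and Hba-a2 had an intensity of 2164 ± 300.3 in parental cells (SD, n = 2) and 3145, 3887, 3008 and 2663 in FBB1.5, FBB1.7, FBB1.10 and FBB1.11. It was higher than parental in FBB1.5 (log2 difference 0.54 ± 0.10, limma's adjusted p = 0.012), FBB1.7 (0.85 ± 0.10, adjusted p = 0.00015) and FBB1.10 (0.47 ± 0.10, adjusted p = 0.027), and not in FBB1.11 (0.30 ± 0.10, adjusted p = 0.25). The call in FBB1.5 ended without FBB1.5 2 (adjusted p = 0.14) and that in FBB1.10 without parental 1 or FBB1.10 2 (adjusted p up to 0.23), and that in FBB1.7 held whichever array was left out. The 3 dimmer alpha-globin probe sets had, from the brightest to the dimmest, adjusted p of 0.017, 0.11 and 0.18 in FBB1.5, 0.00067, 0.039 and 0.0096 in FBB1.7, 0.12, 0.97 and 0.26 in FBB1.10, and none passed in FBB1.11. In FBB1.5 the brightest lost its call without parental 1 or FBB1.5 2 (adjusted p up to 0.17). In FBB1.7 the dimmest lost its call without FBB1.7 2 (adjusted p up to 0.13). In FBB1.7 the middle one lost its call without parental 1, parental 2, FBB1.7 1, FBB1.11 1 or FBB1.11 2 (adjusted p up to 0.31). Calls were gained as well, for the middle one in FBB1.5 and FBB1.11 without FBB1.10 1 or FBB1.10 2. The brightest of the 3 gained its call in FBB1.10 without parental 2. The probe set shared by the adult beta-globin genes had 920.1 ± 77.9 in parental cells and 899 to 1117 in the subclones, and passed in none. The probe sets of the embryonic genes Hbb-y and Hbb-bh1 did not pass the filter, with line means of at most 15.4. A difference in these transcripts was not detectable at this signal. Hba-x, the embryonic alpha-like gene, had 46.7 ± 3.37 in parental cells and 45.6 to 66.1 in the subclones and passed in none. The bright alpha-globin probe sets are annotated to both genes, so neither is named singly.

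Among 22 gene lists fixed before the data were examined, 2 passed the competitive gene set test on the comparison of all tagged arrays with parental. Mast cell and basophil genes were lower (adjusted p = 0.00087, and adjusted p = 0.010 with an estimated correlation), with a median log2 difference of -0.67 over 5 measured members. None of the 5 passed over all genes tested and 3 were lower adjusted over the list alone. Its members include Cpa3, a mast cell carboxypeptidase, at 99 ± 9.43 in parental cells (SD, n = 2) and 48.4 to 67.1 in the subclones, and Gzmb, granzyme B, at 269 ± 11.3 and 129 to 250.0. Cma1, a chymase, stood at 293 ± 43.1 in parental cells, 447 in FBB1.5 and 31.2 in FBB1.7, and Mcpt4 at 51.8 ± 4.02, with 32.8 in FBB1.7 and not above the table median in the other 3 subclones. Cma1, Mcpt4 and Gzmb lie in the same protease cluster on chromosome 14, and the remaining member, Tpsb2, was above 0. The list call thus rests largely on neighbouring genes, as it does for this list in single subclones below. Genes of mitosis and S phase were higher as a list (adjusted p = 1.4e-06), by a median of 0.15 with 23 of 27 members above 0, among them Pcna (1313 against 1440.5 to 1935) and Cdc20 (1067 against 1273 to 1304). That call was lost with the list's own correlation (adjusted p = 0.13 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. Both calls ended without parental 1, at an adjusted p of 0.12 for each list, and the mast cell call also with no intensity filter (adjusted p = 0.087). Heat shock and unfolded protein response genes (adjusted p = 0.059) and erythroid transcription factors (adjusted p = 0.081) did not pass. Neither passed with an estimated correlation (adjusted p = 0.36 and 0.34 with an estimated correlation). In the fit of 5 line means both passed, at adjusted p of 0.0017 and 0.034, and with an estimated correlation heat shock genes did (adjusted p = 0.00070) and erythroid transcription factors did not (adjusted p = 0.43). Without FBB1.11 2 both passed, at adjusted p of 0.012 and 0.049, and heat shock genes also passed without FBB1.5 2 (adjusted p = 0.042) and globins without FBB1.10 1 (adjusted p = 0.041).

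The adjusted p over the other lists was 0.36 for globins, 0.36 for heme synthesis, 0.71 for iron handling, 0.69 for red cell membrane and surface, 0.72 for NuRD complex, 0.71 for haematopoietic progenitor genes, 0.71 for megakaryocyte and platelet, 0.51 for granulocyte and macrophage, 0.71 for B lymphoid, 0.51 for T and NK lymphoid, 0.51 for CDK inhibitors, 0.81 for p53 targets and apoptosis, 0.75 for interferon response, 0.71 for glycolysis and hypoxia, 0.24 for sterol synthesis, 0.71 for ribosomal proteins and 0.13 for immediate early genes. The globin test covered 3 of 11 members, each read by a dim probe set of its own. The bright alpha- and beta-globin probe sets, shared between genes, had no part in it. Of the blood lineage lists, none but mast cell and basophil passed. Gata2, a progenitor transcription factor, had 264 ± 5.04 in parental cells (SD, n = 2) and 139.6 to 207 in the subclones, and it was lower adjusted over the list alone, though not over all genes (adjusted p = 0.35). Gata2 fell in FBB1.7 (adjusted p = 0.00048) and FBB1.10 (adjusted p = 0.023) in the fit of 5 line means. Among NuRD complex members, a chromatin remodelling complex, Chd3 had 348 in parental cells and 205 in FBB1.5 (adjusted p = 0.0044). Bcl11a, a list of 1 gene, is too short for the list test.

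FBB1.5 differed from parental in many genes of chromosome 14. Vdac2, a mitochondrial porin encoded there, rose from 1410.4 ± 72.9 to 3012 ± 40.3 (SD, n = 2), 2.12-fold (adjusted p = 5.3e-06). Cwh43 rose from 21.9 ± 4.07 to 138 ± 12.4, at least 4.51-fold (adjusted p = 4.7e-05), and Pcare from 6.77 to 54.6, at least 1.78-fold (adjusted p = 0.0081), both at or below the table median on 2 of 2 parental arrays. Ttll4, a tubulin-modifying enzyme gene, decreased from 369 ± 27.6 to 146 ± 30.2 (adjusted p = 0.00052), E330020D12Rik from 285 to 115 (adjusted p = 0.0029) and Foxb2 from 94.1 to 35.3 (adjusted p = 0.029). These 6 passed in no other subclone, and 5 of them differed between subclones in the F test, Foxb2 being the exception (adjusted p = 0.067). Pcare lost its call without FBB1.5 2 (adjusted p = 0.095) and Foxb2 without parental 2 or FBB1.5 2 (adjusted p up to 0.26). In all, 507 probe sets, 323 higher and 184 lower, passed limma's test. Quantile normalization gave 298 higher and 259 lower. Of the 431 called probe sets with a known chromosome, 132 (30.6%) lie on chromosome 14, which holds 3.42% of the tested ones, and 128 of these were higher. Over 141 chromosome 14 genes with a mean intensity above 200, the median log2 difference was 0.42 (1.34-fold) and 129 genes were above 0, and without chromosome 14 genes 302 probe sets passed. Both chromosome values were computed after the data were seen. Sterol synthesis genes were higher as a list (adjusted p = 1.3e-06, and adjusted p = 0.021 with an estimated correlation), 3 of 19 over all genes tested and 9 adjusted over the list alone, among them Fdps (481 to 731, adjusted p = 0.039) and Msmo1 (170.0 to 273, adjusted p = 0.022). Mitosis and S phase genes were higher as a list (adjusted p = 0.0020, and adjusted p = 0.43 with an estimated correlation), with no member past the threshold over all genes. The count was 22 without the intensity trend in the variance, 810 without parental 1, 275 without FBB1.5 1, the array with the raised actin ratio, and 184 without FBB1.5 2.

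**Figure D3:**
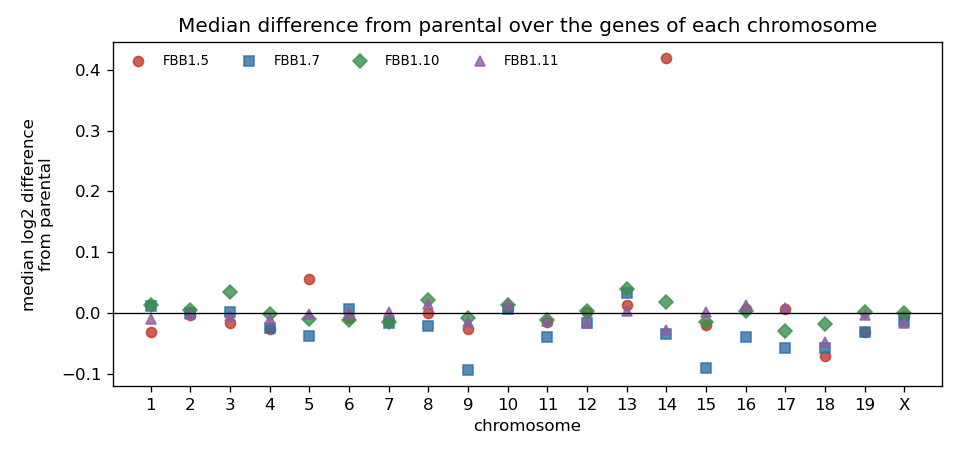
Median log2 difference from parental cells over the genes of each chromosome with a mean intensity above 200, for each of the 4 subclones (symbols). Chromosome 14 in FBB1.5 stands at 0.42 and every other median lies between -0.095 and 0.057.

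FBB1.7 differed most from parental, with lower mast cell proteases and higher chaperones of the endoplasmic reticulum. Mcpt2 fell from 5453 ± 736 to 673 ± 60.8 (SD, n = 2), 7.92-fold (adjusted p = 4.0e-09), and Cma1 from 293 ± 43.1 to 31.2 ± 2.52 (adjusted p = 5.6e-06). Hsp90b1, the chaperone of the endoplasmic reticulum also called Grp94, rose 1.75-fold to 1779.6 ± 24.8 (adjusted p = 2.0e-05), Hspa5 from 854 to 1402 (adjusted p = 0.00023) and Pdia6 from 491 to 1150.2 (adjusted p = 2.9e-05). The inducible heme oxygenase Hmox1 rose 2.69-fold, from 171 to 489 ± 38.9 (adjusted p = 1.5e-05). Heat shock and unfolded protein response genes were higher as a list (adjusted p = 0.0016, and adjusted p = 0.0013 with an estimated correlation), with 5 of 19 members up and 2 down over all genes tested, and 7 up and 2 down adjusted over the list alone. After quantile normalization the adjusted p was 0.054, which misses the threshold, and 0.049 with an estimated correlation. Hsph1, a cytosolic heat shock protein gene of this list, fell from 1021 to 649 (adjusted p = 0.00047). Mitosis and S phase genes were higher (adjusted p = 1.6e-08, and adjusted p = 0.048 with an estimated correlation), 9 of 27 over all genes and 12 adjusted over the list alone, such as Mcm5, a subunit of the replicative helicase (895 to 1462, adjusted p = 0.00043), and Pcna (adjusted p = 0.00074). The list call with its own correlation ended under other scalings, at adjusted p = 0.085 with an estimated correlation after quantile normalization and 0.082 with each array centred on its median. Glycolysis and hypoxia genes passed (adjusted p = 0.0095) but not with their own correlation (adjusted p = 0.55 with an estimated correlation), nor after quantile normalization (adjusted p = 0.30). Of its 21 members 5 were higher and 1 lower, Ldha among the higher (adjusted p = 0.00012). The mast cell and basophil list was lower (adjusted p = 0.00011, and adjusted p = 0.0095 with an estimated correlation), with 3 of 5 members past the threshold over all genes and 4 adjusted over the list alone. Passing here and in no other subclone, Elovl6, Rhox9 and Zfp346 were the 3 highest by the fit and Aplf, 1700129C05Rik and Espn the 3 lowest. The log2 difference was 1.51 ± 0.42 for Elovl6 and 1.00 ± 0.26 for Zfp346, and Aplf fell 2.82-fold. Rhox9, at or below the table median on both parental arrays, rose at least 1.42-fold, and 1700129C05Rik and Espn, at or below it on both FBB1.7 arrays, fell at least 1.25-fold and 2.60-fold. Of these 6, Espn alone differed between subclones in the F test (adjusted p = 0.0088), and it alone passed whichever array was left out. Elovl6 lost its call without parental 1, parental 2 or FBB1.7 2, Rhox9 without FBB1.7 1, Zfp346 without parental 2, FBB1.7 1 or FBB1.7 2, 1700129C05Rik without parental 2 or FBB1.7 1 and Aplf without any array but parental 1, with adjusted p up to 0.29, 0.14, 0.16, 0.074 and 0.35. The log2 difference of Aplf was -0.37 without parental 2 and -2.62 without parental 1, and that of Elovl6 0.91 without FBB1.7 2 and 2.11 without FBB1.7 1. In all, 2519 probe sets, 1140 higher and 1379 lower, passed. The split turned to 1332 higher and 1139 lower without parental 1, to 850 higher and 758 lower without parental 2 and to 531 higher and 328 lower with the actin ratio as a covariate. The count was 1187 without the intensity trend in the variance, 1608 without parental 2, 859 and 1071 without FBB1.7 1 or 2, and 859 with the actin ratio as a covariate.

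FBB1.10 shared the raised chaperones of FBB1.7 and its lower mast cell proteases. Hsp90b1 rose 1.61-fold to 1639.9 ± 12.1 (SD, n = 2, adjusted p = 0.00031), Hspa5 from 854 to 1557 (adjusted p = 0.00030) and Calr, calreticulin, from 3345 ± 184 to 5043 ± 159 (adjusted p = 0.00030). Asns, asparagine synthetase, rose from 2552 to 3604 (adjusted p = 0.0019), and heat shock and unfolded protein response genes were higher as a list (adjusted p = 4.9e-09, and adjusted p = 1.2e-10 with an estimated correlation), 6 of 19 members over all genes tested and 10 adjusted over the list alone, with 1 lower, Hsph1 (adjusted p = 0.024). Mcpt2 fell to 2096 ± 368 (adjusted p = 0.00011) and Cma1 to 82.7 ± 9.14 (adjusted p = 0.0013). In the mast cell and basophil list 3 of 5 members were lower over all genes (adjusted p of the list = 1.5e-07, and adjusted p = 0.00021 with an estimated correlation). Erythroid transcription factors were lower (adjusted p = 0.016), a call lost with an estimated correlation (adjusted p = 0.33), and no single one passed over all genes. Mitosis and S phase genes were higher as a list (adjusted p = 0.00017, and adjusted p = 0.27 with an estimated correlation), 1 of 27 over all genes. Passing in no other subclone, Dclk2, Kctd9 and Prep were the 3 highest (log2 difference 0.76 ± 0.18, 0.72 ± 0.13 and 0.44 ± 0.10) and 1700047M11Rik, Ermard and Plxnd1 the 3 lowest by the fit. Ermard had a log2 difference of -1.05 ± 0.25, and 1700047M11Rik and Plxnd1, at or below the table median on both FBB1.10 arrays, fell at least 1.09-fold and 1.32-fold. Of these 6, Kctd9 and Plxnd1 differed between subclones (F test, adjusted p = 0.025 and 0.0077). Each of these 6 calls ended without parental 2, FBB1.10 1 or FBB1.10 2, and some without other arrays, with adjusted p up to 0.31. In all, 450 probe sets, 270 higher and 180 lower, passed. The split turned to 197 higher and 224 lower after quantile normalization, and to 188 and 198 with each array centred on its median. The count was 1 without the intensity trend in the variance, 1194 without parental 1, 262 without parental 2, 108 and 113 without FBB1.10 1 or 2, 288 and 286 without FBB1.11 1 or 2, and 125 with the actin ratio as a covariate.

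FBB1.11 had the fewest differences, except without the intensity trend in the variance (8, against 1 in FBB1.10), and Bex4 fell below the table median there. Bex4 fell from 176 ± 2.42 to 14.3 ± 0.537 (SD, n = 2), at or below the table median on both arrays and at least 5.78-fold (adjusted p = 5.6e-07), and it also fell in FBB1.5, to 94.1 (adjusted p = 0.012). In FBB1.11 Mcpt2 fell to 1487 ± 44.7 (adjusted p = 1.8e-06), Cma1 to 44.7 ± 11.9 (adjusted p = 6.4e-05) and Gzmb to 129 ± 15.8 (adjusted p = 0.0075). Syt1, a synaptotagmin gene, rose from 23.2 ± 1.22 to 68.2 ± 9.69, at least 2.22-fold over parental arrays that both lay at or below the table median (adjusted p = 0.030), and Lgals1, galectin-1, from 4717 ± 202 to 5664 ± 57.8 (adjusted p = 0.047). Nrgn decreased from 467 ± 14.6 to 217 ± 22.0 (adjusted p = 0.0040), Csf2rb, the shared cytokine receptor chain, from 397 to 209 (adjusted p = 0.043) and the cholesterol transporter gene Abca1 from 266 to 153 (adjusted p = 0.047). These last 5 passed in no other subclone, and of them Syt1, Nrgn and Csf2rb differed between subclones in the F test. Each of the 5 calls ended without FBB1.11 1 and each but Nrgn also without FBB1.11 2, and some without other arrays, with adjusted p up to 0.39. The mast cell and basophil list was lower (adjusted p = 2.6e-13, and adjusted p = 1.3e-07 with an estimated correlation), 2 of 5 members over all genes tested, and mitosis and S phase genes were higher as a list (adjusted p = 0.00026, and adjusted p = 0.29 with an estimated correlation). In all, 47 probe sets, 19 higher and 28 lower, passed limma's test, and quantile normalization gave 14 higher and 35 lower. The split turned to 349 higher and 86 lower without parental 1 and to 56 higher and 39 lower without parental 2. The count was 8 without the intensity trend in the variance, 435 and 95 without parental 1 or 2, 10 and 22 without FBB1.11 1 or 2, 30 and 28 without FBB1.7 1 or 2, 72 without FBB1.5 2, and 16 with the actin ratio as a covariate.

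The 4 subclones, which carry the same construct, differed from each other, and among the genes with the smallest p were the protease genes Mcpt2 and Cma1, the chaperone genes Hsp90b1 and Calr, Hmox1 and Gpx1. Mcpt2 and Cma1 were highest in FBB1.5 and lowest in FBB1.7, 7.23-fold and at least 13.5-fold apart (moderated F test, adjusted p = 9.7e-08 and 2.7e-06). Cma1 lay at or below the table median on 1 of 2 FBB1.7 arrays. Both genes lie on chromosome 14, whose bright genes had a median log2 difference from parental of 0.42 in FBB1.5. How much of these spans goes with that was not tested. Hsp90b1 and Calr were higher in FBB1.7 and FBB1.10 than in FBB1.5, 1.91-fold and 1.72-fold between extremes (adjusted p = 1.3e-05 and 1.3e-05), and so were Hmox1 (3.17-fold, adjusted p = 1.2e-05) and Gpx1, a glutathione peroxidase (1.56-fold, adjusted p = 2.8e-05). Thy1, a surface glycoprotein, was lowest in FBB1.5 at 330.3 ± 61.2 (SD, n = 2) and highest in FBB1.7 at 939.8 ± 31.0 (adjusted p = 1.1e-05). Bex4 was lowest in FBB1.11 (adjusted p = 3.6e-07), and Vdac2 and Cwh43 were highest in FBB1.5 (adjusted p = 1.5e-06 and 1.3e-05). In all, 1814 probe sets of 1299 named genes differed. These 10 genes passed whichever array was left out. The count was 951 without FBB1.5 1, 848 and 1003 without FBB1.7 1 or 2 and 1186 without FBB1.11 1.

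A few transcripts passed in all 4 subclones, 10 probe sets higher and 6 lower. Igf1r, the receptor of insulin-like growth factor 1, rose from 187 ± 2.54 (SD, n = 2) to between 293 and 335, with adjusted p from 0.0017 to 0.015. Eif5a, a translation factor gene, rose on 2 probe sets in each subclone, the brighter from 5327 ± 107 to between 6662 and 8662. Atp5a1, a subunit of ATP synthase, rose from 4268 to between 5200.5 and 6604, and Prmt5, an arginine methyltransferase gene of chromosome 14, from 577 to between 775 and 1141. Kif3b, Phf3, Trip11 and Dusp7 also rose, and H1f2, Ube2h, Cog1 and 1 probe set of Ndrg1 fell. The others are 1 probe set shared by Prdx1 and Gm21399 and 2 without a gene name. Because all subclones were set against the same 2 parental arrays, part of this overlap can come from those arrays, which are too few to split. In 3 or more subclones 44 probe sets were higher and 34 lower. In 20 simulated data sets with no effect the number was 0, which says little, since at most 7 probe sets passed in any of them and neither clone variance nor a shift of a parental array was simulated. Of the 16, 8 still passed in all 4 without parental 2 and 2 with the actin ratio as a covariate. The number in all 4 was 0 to 215 with 1 array left out, with 215 without parental 1, 34 without parental 2, 8 without FBB1.5 2, 7 without FBB1.7 1, 8 without FBB1.7 2, 7 without FBB1.10 2, 0 without FBB1.11 1 and 4 without FBB1.11 2. FBB1.7 and FBB1.10 shared 242 higher and 149 lower probe sets, where independent lists would share 12.3 and 9.90. Across genes their fold changes had r = 0.724 and a covariance of 0.0511, against r = 0.50 and 0.0138 from shared parental arrays alone when all arrays vary alike. The parental pair differed more than the other pairs, and with each pair's own spread, an alternative chosen after the data were seen, shared parental arrays alone give r = 0.617 and a covariance of 0.0216. Over the other 5 pairs r was 0.411 to 0.636 and the covariance 0.0257 to 0.0385, where that spread gives r of 0.568 to 0.627.

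Each line was also set against the other 4, with the cell line as a block, to see whether the parental line stood further from the rest than a single subclone did. FBB1.5, the line with the chromosome 14 difference, gave 155 probe sets (124 higher), FBB1.7 55 (45 lower), FBB1.11 2, and FBB1.10 and parental cells 0 each by limma. At an unadjusted p under 0.05 there were 3189 for FBB1.7, 2190 for parental cells, 2084 for FBB1.5, 521 for FBB1.10 and 414 for FBB1.11. In the fit of 5 line means the counts were 2090 for FBB1.7, 1126 for FBB1.5, 887 for parental cells, 52 for FBB1.10 and 43 for FBB1.11. Ranking 5 lines cannot give a share under 0.05, so it excludes nothing about chance.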

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

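The tests on parental 2, on differences between clones, on the neighbouring genes and on Cpa3 were chosen only after the results were seen, and the test on the Bcl11a level was written before its result was seen. Among 10 quality measures of the 8 tagged arrays, 1 array stood apart by Dixon's test, FBB1.5 1 with an actin 3' to 5' ratio of 1.47. Chance flags about 1 in 20 such groups.

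The effect against parental differed between the 4 subclones, by the moderated F test, for 1814 probe sets. The 10 genes with the smallest p spanned, from the lowest to the highest subclone mean, 7.23-fold for Mcpt2, at least 7.51-fold for Bex4, 2.17-fold for Vdac2, at least 13.5-fold for Cma1, 2.78-fold for Thy1, 3.17-fold for Hmox1, 1.91-fold for Hsp90b1, 1.72-fold for Calr, at least 4.51-fold for Cwh43 and 1.56-fold for Gpx1. The lowest subclone lay at or below the table median on 2 of 2 arrays for Bex4, 2 of 2 for Cwh43 and 1 of 2 for Cma1. The Bcl11a probe set that rose in the tagged cells spanned 2.85-fold, and another Bcl11a probe set, lowest in FBB1.7, 1.58-fold. Bex4 was lowest in FBB1.11 and Vdac2 highest in FBB1.5.

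The mean of the subclones differed from parental for 887 probe sets when the spread was that between arrays of a line, and for 0 by limma with the line as a block (2190 at an unadjusted p under 0.05). RNA quality of parental 2 is argued against as the source of all these calls, since 270 of them also passed in the same direction without that array, where 351 passed and 17.6 false calls would be allowed. RNA quality of parental 2 thus stays open, and 198 probe sets, 174 of them among these 887, passed with the actin ratio as a covariate. An effect graded with the Bcl11a probe set would give a larger median change in FBB1.10 and FBB1.11, where that probe set is highest. The median was 0.377 there and 0.463 in FBB1.5 and FBB1.7, a difference of -0.087, so no larger change was seen. The 887 were chosen by the mean over the same 4 subclones, and FBB1.7 had 2519 calls where FBB1.11 had 47. Large changes of FBB1.7 thus enter the set, and its median cannot argue against a graded effect. That probe set may also misread the construct. Differences between clones remain open, since 2 of the other 4 lines, FBB1.5 and FBB1.7, gave at least as many calls as the parental line in the same fit. The tagged protein acting above some level also stays open, untested.

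Mcpt2 and Cma1 fell in FBB1.7, FBB1.10 and FBB1.11 and did not pass in FBB1.5, where Mcpt4 instead passed as lower (18.7, not above the table median, adjusted p = 0.025), and these genes and Gzmb lie in a protease cluster on chromosome 14. Loss of the surrounding segment was tested on the 20 tested genes beside the cluster, which had a median log2 difference of -0.0050 in FBB1.7. The lowest, Khnyn, stood at -0.56, against -2.98 for Mcpt2, so none of the 20 fell as deeply. No minimum beyond the intensity filter was set for them, and dim genes can hardly fall. In FBB1.5 their median was 0.23, against 0.42 over the bright genes of chromosome 14. The median therefore cannot argue against the loss of some copies of the segment. Khnyn (-0.56, -0.31 and -0.54) and Nynrin (-0.46, -0.50 and -0.14), on one side of the cluster, were below 0 in FBB1.7, FBB1.10 and FBB1.11. The nearest tested gene on that side, Sdr39u1 (0.12, 0.12 and 0.054), was above 0 in these subclones. So was Atp12a (0.47, 0.14 and 0.23), the nearest on the other side. A loss within the cluster or of some copies next to it stays open. The labels name only a MEL cell line and its subclones, so they give no source of mast cells in these cultures. Fewer mast cells, against a change within the cells, was tested all the same and not decided. Cpa3, a mast cell gene outside the cluster, fell in FBB1.7 by 0.629 of the log2 fall of Mcpt2 after background subtraction. That lies between the bounds set for either reading, at levels near the background (99 in parental cells and 48.4 in FBB1.7). On the log2 scale used elsewhere that share was 0.283, and it was 0.186 for Gzmb and 0.159 for Mcpt4, which are under the bound against fewer mast cells but can be held up by background or by expression of the MEL cells themselves, while Tpsb2 stood at 38.7 in parental cells and 54.2 in FBB1.7.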

How the results depend on the processing

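Alternatives with the actin ratio, without 2 arrays together or without chromosome 14 genes were chosen after the data were seen, as were the other scalings for list tests. Of 180 counts under alternatives, 114 stayed within 1.5 times the value reported. No named gene or list changed direction while passing, and named genes kept their side of the threshold in 2128 values, lost it in 329 and gained it in 14. The cause was not tested, except that a 1.5-fold minimum removes calls by construction. For tagged against parental (0), calls numbered 1 with no filter, 3 with no line block, 31 without both FBB1.5 arrays, 3 without FBB1.5 1 and parental 2 together, 887 in the fit of 5 line means, 198 in it with the actin ratio, and 0 to 128 with 1 array left out. The mean of the 4 subclones (887) gave 550 without FBB1.5 1 and parental 2, and 351 to 1314 with 1 array left out.

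FBB1.5 against parental (507) gave 201 with no filter, 22 without the variance trend, 254 at 1.5-fold, 302 without chromosome 14 genes, and 184 to 810 with 1 array left out. FBB1.7 against parental (2519) gave 1628 with no filter, 1187 without the variance trend, 952 at 1.5-fold, 859 with the actin ratio, and 859 to 2637 with 1 array left out. FBB1.10 against parental (450) gave 119 with no filter, 1 without the variance trend, 189 at 1.5-fold, 125 with the actin ratio, and 108 to 1194 with 1 array left out. FBB1.11 against parental (47) gave 16 with no filter, 8 without the variance trend, 31 with pseudocount 1, 157 without FBB1.5 1 and parental 2, 16 with the actin ratio, and 10 to 435 with 1 array left out. Differences between the 4 subclones (1814) gave 985 with no filter, 483 without the trend, 1094 at 1.5-fold and 848 to 2402 with 1 array left out.

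Probe sets called in all 4 subclones (16) numbered 1 with no filter, 0 without the trend, 5 with the actin ratio, 31 with the replicate block and 56 without FBB1.5 1 and parental 2. Replicate numbers do not pair the arrays, as deviations of same-numbered arrays correlated at -0.16 to 0.18 and 1 of 10 pairs was over 0.1. The replicate block moved FBB1.11 from 47 to 121 calls and the probe sets called in all 4 subclones from 16 to 31, and left the counts of the other comparisons within 1.5 times, with 0 for tagged against parental. For each line against the other 4, the fit of 5 line means gave 887 for parental, 1126 for FBB1.5, 2090 for FBB1.7, 52 for FBB1.10 and 43 for FBB1.11, with 2 subclones at or above the parental count. With the line as a block all 4 met that automatically, because the parental count was 0. No filter gave 1 for parental and 4 for FBB1.7. Of the preset gene lists (2 called), 1 passed with estimated correlations, 4 in the fit of 5 line means, 1 with no filter and 0 to 4 with 1 array left out. In single subclones, quantile normalization and median centring kept 22 list calls, counted once per scaling, ended 2 (both in FBB1.7) and added glycolysis and hypoxia, lower in FBB1.5 (adjusted p = 0.0047 and 0.036, against 0.068), a call that neither gave with an estimated correlation (adjusted p = 0.42 and 0.64 with an estimated correlation). Probe sets near the table median carry little signal over background, so their differences are the least certain.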

Other observations

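The 3 tests on the chromosome 14 pattern, the list tests in single subclones and the grouping by chromosome were chosen after the data were seen. In FBB1.7, genes of the red cell membrane moved both ways, 4 higher and 3 lower of 21 over all genes tested, and the list did not pass (adjusted p = 0.72). The water channel gene Aqp1 rose from 475 to 732 (adjusted p = 0.0015), the spectrin gene Sptb from 186 to 353 (adjusted p = 0.0096) and Rhag, of the Rh complex, from 332 to 479 (adjusted p = 0.011), by limma with 2 arrays per line. The adducin genes Add1 and Add2, of the membrane skeleton, fell from 753 to 476 (adjusted p = 0.0013) and from 562 to 365 (adjusted p = 0.0025). Of the erythroid transcription factors, 6 of 24 fell in FBB1.7, with no list call (adjusted p = 0.064), among them Cbfa2t3 from 1171 to 787 (adjusted p = 0.00090), the GATA1 cofactor gene Zfpm1 from 1041 to 759 (adjusted p = 0.0040) and Tcf3 from 228 to 142 (adjusted p = 0.0081). Junb fell from 179.8 to 92.4 (adjusted p = 0.00090), and 3 of 11 immediate early genes passed as lower (adjusted p of the list = 0.22). Ddit3, a stress-induced transcription factor gene, fell in FBB1.5 from 1995 to 1379.9 (adjusted p = 0.020) and differed between subclones (F test, adjusted p = 0.0010).

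Genes were grouped by chromosome, 1 probe set per gene with a mean intensity above 200, over 4120 genes. In FBB1.5 the 141 genes of chromosome 14 had a median log2 difference from parental of 0.42, with the quartiles of genes from 0.20 to 0.56, and 129 genes were higher (cameraPR adjusted over 80 chromosome and subclone pairs, p = 3.7e-50, and adjusted p = 6.2e-11 with an estimated correlation). In the order of the genes along the chromosome, the 8 successive segments had medians of 0.44, 0.43, 0.48, 0.43, 0.45, 0.35, 0.41 and 0.18, from the segment of Pdhb to Adk to that of Slc25a30 to Pcca. After quantile normalization the median was 0.42. On chromosome 5 the first 2 of 8 segments, which run from Cdk6 to Man2b2, had medians of 0.26 and 0.32 in FBB1.5, against -0.055 to 0.085 in the other 6. Chromosome 5 as a whole passed (adjusted p = 0.0085) but not with an estimated correlation (adjusted p = 1.0).

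RNA quality of array FBB1.5 1 is argued against as the source of the chromosome 14 pattern, because array FBB1.5 2 alone showed a median of 0.36 against 0.45 in FBB1.5 1. Action of the tagged protein on these genes is argued against, since the highest chromosome 14 median among the other 3 subclones with the same construct was 0.018. Misreading by single probe sets is argued against, because the 38 second probe sets of chromosome 14 genes had a median of 0.48 with 34 above 0. They had no part in the median of 0.42, though any that passed count among the called probe sets of chromosome 14. Extra copies of chromosome 14 in FBB1.5 remain an untested hypothesis, since second probe sets rise with whatever raises the transcripts and DNA copy number was not analysed here.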
